A study of Mus musculus with 18 samples.

How the data were processed

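RNA was sequenced from 18 tibialis anterior muscles of mice, taken 36 days after ligation of the femoral artery of 1 hindlimb. The labels place each library in 1 of 4 groups by genotype (WT, control, or BKO, doxycycline-induced deletion of Bmal1 in skeletal muscle) and limb (ligated, or intact on the other side). They give the Cre genotype the other way round, +/+ for controls and -/- for knockouts, so the direction of each genotype comparison rests on the group names. The time of day of collection is not given in the sources used here. The libraries were made with a TruSeq stranded total RNA kit, per the labels' protocols. Trimmomatic 0.33, STAR 2.5.2, RSEM 1.3.3 and DESeq2 (version not given in the sources used here) and the build mm10 are named per the submitters' processing notes, without their order or role. The annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes, or of near-identical copies, are uncertain in their split.

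The authors' deposited values are normalized counts, a signal per gene and library that is not corrected for gene length. Each value was a whole number divided by 1 size factor per library: within a tolerance of 0.001, 100% of the values in every library came out as whole numbers. The sources used here do not say whether these are counted reads or rounded estimates of them. They are called reads here. In WT intact library 6 and BKO ligated library 2 that factor lay close to 1, so whole reads tell less there. The reads recovered this way gave the depth, 14.1 to 25.6 M reads per library (M for mega), which leaves out reads not assigned to a gene. The table holds 20922 genes, 20643 of them with a symbol. The number of reads limits the precision of low genes, and reads without molecular identifiers are not independent molecules. The labels do not say whether samples with 1 number came from 1 mouse, nor in so many words that each came from a separate animal, so p-values measure the spread between these samples. Over the 32 pairs of libraries of 1 group, the recovered reads differed by more than sampling noise (chi-square per degree of freedom 10.4 to 285), so no library was treated as a repeat of another. Genes with most reads, such as the mitochondrial ribosomal RNA mt-Rnr2, can weigh most in this value, so it does not measure how many genes differed.

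The unit was assumed to be normalized counts before the data were examined, as were the groups, tests, gene lists, the rule for named genes and the settings to be varied. Genes with a mean normalized count of at least 10 over the 18 libraries (12262 genes) were tested on log2(normalized count + 1) with limma 3.58.1 in R 4.3.3. One fit held a mean for each of the 4 groups, with eBayes and an intensity trend, and 5 comparisons were drawn from it. They are ligated against intact limbs in WT and in BKO, BKO against WT in intact and in ligated limbs, and the interaction, which is the ligation effect in BKO minus that in WT. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(normalized count + 1) scale, which understates changes of low genes. The error beside a log2 fold change is its standard error from limma, and the error beside a group mean is the SD over 5 intact or 4 ligated libraries.

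The 30 gene lists covered the clock (genes activated by BMAL1-CLOCK, genes repressed by REV-ERB), muscle state (myogenic and regeneration, denervation, atrophy, fast fibre and slow fibre genes), vessels (endothelial markers, angiogenic factors, smooth muscle and pericyte markers) and immune cells (macrophage markers, antigen presentation by MHC class II, cytokines and chemokines, lymphocyte and neutrophil markers). They also covered stroma and fat (fibro-adipogenic progenitor, extracellular matrix, tendon and adipocyte genes), metabolism (oxidative phosphorylation, tricarboxylic acid cycle, glycolysis, fatty acid oxidation), stress (hypoxia, oxidative stress, interferon, immediate early and cell cycle genes), Schwann cells and blood cells. Lists with at least 3 tested members, 28 of the 30, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera compares a list with all other genes. Alternatives were a correlation estimated from the data and limma's fry, which tests a list against no change and not against other genes.

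Genes were named by a rule: Bmal1, the 10 genes with the largest rise and the 10 with the largest fall per comparison, and up to 4 members with the smallest p of each list described. The genes with the largest changes had to have a mean of at least 50 in the groups compared and no overlap of the values (overlap was allowed for the interaction), and predicted genes were left out. Of the genes this rule gave, those printed are ones whose call stayed when any 1 library was left out, a choice made after their values were seen; Bmal1 for ligation in BKO is the exception. Gene positions are those of GENCODE vM21 on mm10.

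Counts of genes past the test were computed again with pseudocounts of 0.5 and 5, no filter or a filter at 50, and quantile or upper-quartile scaling. Other settings were only the libraries compared, robust eBayes, array weights, a log2 fold change of at least 1, and each library left out in turn. Further ones were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and a fixed or random block for the sample number. edgeR called 5049, 5933, 2298, 1119 and 748 genes and DESeq2 5100, 6063, 2447, 1313 and 1183 for ligation in WT and in BKO, knockout in intact and in ligated limbs, and the interaction. A correction for transcript length and GC content, and a fit without the 2 BKO ligated libraries with most reads from mt-Rnr2, were added after seeing the data. Calls of named genes were not followed under these 2 settings, edgeR, DESeq2 or the random block. List calls were followed only with an estimated correlation, fry, quantile normalization, the fixed block, the correction for length and GC content, and each library left out. The steps were tested on simulated data with known changes in 200 genes. Of the genes changed 4-fold, 97.0% were recovered for ligation in WT, 95.5% for ligation in BKO, 98.5% for knockout in either limb and 90.9% for the interaction. At 2-fold these shares were 64.2%, 74.6%, 79.1% (intact), 56.7% (ligated) and 37.3%, so smaller interactions can be missed. Fewer genes were changed in the simulation than passed in the data, which makes the adjusted p threshold stricter there, so these shares need not hold for the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.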

Results

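The transcriptome of the tibialis anterior, a muscle of the lower hindlimb, was measured in mice whose femoral artery was ligated on 1 side, a model of peripheral artery disease. The muscle of the ligated limb and that of the intact limb of the other side were compared in control mice (WT) and in mice with an induced deletion of the clock gene Bmal1 in skeletal muscle (BKO). There were 5 libraries of intact and 4 of ligated muscle for each genotype. Depth was 18.1 ± 2.08 M reads (SD, n = 5) in WT intact, 18.4 ± 3.02 M (SD, n = 4) in WT ligated, 20.6 ± 2.40 M (SD, n = 5) in BKO intact and 21.3 ± 2.90 M (SD, n = 4) in BKO ligated libraries. The main principal component held 42.0% of the variance of the tested genes and set all ligated libraries apart from all intact ones. The next held 11.3% and set BKO apart from WT. The mitochondrial ribosomal RNA mt-Rnr2 took 32.8% ± 1.11 (SD, n = 5) of the reads in WT intact, 41.1% ± 3.20 (SD, n = 4) in WT ligated, 35.3% ± 1.12 (SD, n = 5) in BKO intact and 47.9% ± 6.91 (SD, n = 4) in BKO ligated libraries.

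Bmal1 (symbol Arntl, ENSMUSG00000055116, chromosome 7, 113207465 to 113314126 on mm10) encodes the transcription factor that, with CLOCK, drives the circadian clock. In WT intact muscle its normalized counts were 41.3, 66.3, 47.3, 68.4 and 58.2, and in WT ligated muscle 17.0, 12.2, 18.3 and 17.3. In the libraries labelled BKO they were 46.2, 49.5, 50.2, 61.1 and 42.4 in intact muscle and 82.0, 63.8, 69.5 and 64.7 in ligated muscle. The means were 56.3 ± 11.8 (SD, n = 5) in WT intact and 49.9 ± 6.997 (SD, n = 5) in BKO intact muscle. They did not differ by an exact two-sided permutation test (p = 0.373). In ligated muscle the means were 16.2 ± 2.72 (SD, n = 4) in WT and 70.0 ± 8.35 (SD, n = 4) in BKO. The exact permutation p was 0.0286 there, the smallest this design allows. By limma the difference of BKO from WT was -0.16 ± 0.17 on the log2 scale in intact muscle (95% interval -0.51 to 0.20, adjusted p = 0.584) and 2.05 ± 0.19 in ligated muscle (adjusted p = 1.67e-07). The count of a gene sums the reads of all its exons, and the labels do not say which exon was deleted, so the total does not check the labels. These values rest on 265, 72, 273 and 275 reads in WT intact, WT ligated, BKO intact and BKO ligated libraries. The time of day of collection is not given in the sources used here, and the levels of clock genes depend on it.

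**Figure D1:**
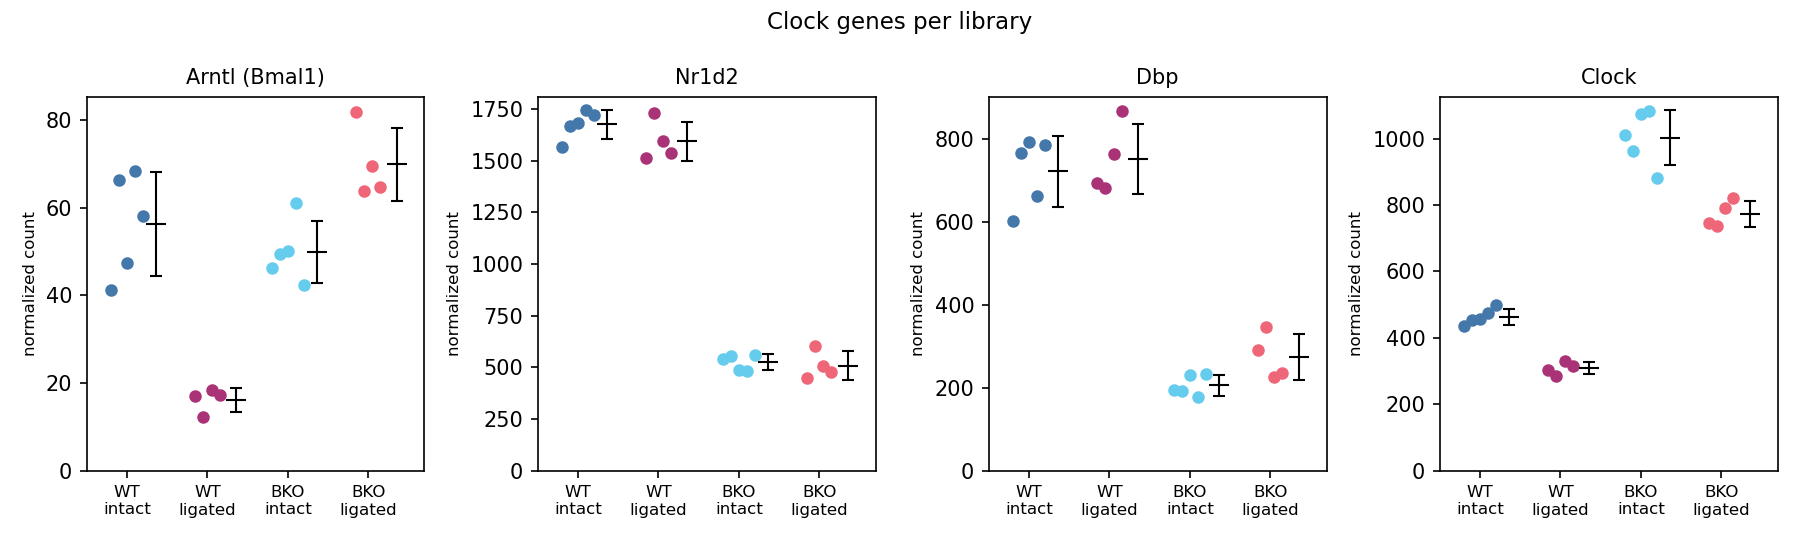
Normalized counts of Arntl (Bmal1), Nr1d2, Dbp and Clock in each of the 18 libraries, by genotype and limb, each axis starting at 0; the bars show the mean ± SD of 5 intact or 4 ligated libraries. Nr1d2 and Dbp were lower and Clock was higher in all BKO than in all WT libraries of the same limb, while Arntl was lowest in WT ligated muscle, at 12.2 to 18.3.

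Knockout in intact limbs asked how the muscle transcriptome differed between genotypes without ischaemia. The output genes of the clock fell, with Nr1d2 going from 1675 ± 69.3 (SD, n = 5) normalized counts in WT to 524 ± 37.8 (SD, n = 5) in BKO and Dbp from 721 ± 84.8 (SD, n = 5) to 205 ± 24.6 (SD, n = 5). Nuclear genes of the respiratory chain were higher, each by less than 2-fold (adjusted p = 0.179 with an estimated correlation). Actc1, the cardiac actin that skeletal muscle makes before birth, rose 13.8-fold, and Car3, the carbonic anhydrase of muscle and fat, fell 11.3-fold. In all, 2246 of 12262 genes passed, 1050 higher and 1196 lower in BKO (111 and 183 by at least 2-fold).

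All 13 genes activated by BMAL1-CLOCK were lower in BKO intact muscle, also when adjusted over the list alone, with a median log2 fold change of -1.44 (camera adjusted p = 1.89e-23; adjusted p = 0.000127 with an estimated correlation). Nr1d2, which encodes the repressor REV-ERB beta (chromosome 14, 18204054 to 18239127), changed by -1.68 ± 0.08. Per1, a repressor of BMAL1-CLOCK, changed by -2.03 ± 0.13, the transcription factor Dbp (chromosome 7, 45705088 to 45710203) by -1.81 ± 0.12 and its relative Tef by -1.16 ± 0.09. Of 6 genes repressed by REV-ERB, 4 were higher and 1 lower, also over the list alone (camera adjusted p = 0.0186; adjusted p = 0.179 with an estimated correlation). Clock (chromosome 5, 76209868 to 76304792) rose by 1.11 ± 0.07, from 463 ± 23.9 (SD, n = 5) to 1003 ± 83.8 (SD, n = 5) normalized counts. Nfil3, a repressor of clock output genes, rose by 1.21 ± 0.14, Npas2, a CLOCK paralog, by 2.49 ± 0.63, and Rora, an activator of Bmal1, fell by 0.81 ± 0.09. Npas2 lay near the filter, at 4.42 ± 6.87 (SD, n = 5) in WT and 17.8 ± 4.76 (SD, n = 5) in BKO, and its values overlapped between the groups.

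All 34 oxidative phosphorylation genes were higher in BKO intact muscle, also over the list alone, with a median of 0.50 (camera adjusted p = 9.42e-25; adjusted p = 0.179 with an estimated correlation). Cox5a of complex IV changed by 0.62 ± 0.08 and Atp5o of the ATP synthase by 0.57 ± 0.07. Of 14 tricarboxylic acid cycle genes, 10 were higher (12 adjusted over the list alone; camera adjusted p = 4.7e-07; adjusted p = 0.281 with an estimated correlation). Sucla2 was at 0.54 ± 0.07 and Sdhb, shared with complex II, at 0.52 ± 0.10. Of 17 fatty acid oxidation genes, 12 were higher (14 over the list alone; camera adjusted p = 1.38e-10; adjusted p = 0.179 with an estimated correlation). Acadm, the medium-chain acyl-CoA dehydrogenase, rose by 0.83 ± 0.09, from 1959 ± 225 (SD, n = 5) to 3479 ± 299 (SD, n = 5) normalized counts. Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose by 1.61 ± 0.19 and Hadha of the trifunctional protein by 0.65 ± 0.08. Shorter transcripts were higher in this comparison: across genes, which are not independent replicates, the log2 fold change had a Spearman correlation of -0.202 with transcript length.

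Among the largest changes in BKO intact muscle, Actc1 (chromosome 2, 114047282 to 114053548) went from 227 ± 94.3 (SD, n = 5) to 3045 ± 939 (SD, n = 5) normalized counts (3.79 ± 0.30, adjusted p = 2.64e-08). Its sequence is close to that of Acta1, the abundant skeletal actin, so its level is uncertain by any reads the counting shared between them. Ighm, the immunoglobulin mu heavy chain (chromosome 12, 113418558 to 113422730), went from 284 ± 68.0 (SD, n = 5) to 2523 ± 729 (SD, n = 5) (3.12 ± 0.26, adjusted p = 5.35e-08). The cell cycle inhibitor Cdkn1a rose by 2.96 ± 0.32, the phosphatase Dupd1 by 2.52 ± 0.12, the sarcomere protein Mybph by 2.17 ± 0.22 and the transcription factor Tead4 by 2.07 ± 0.17. Car3 (chromosome 3, 14863512 to 14872523) went from 16166 ± 2429 (SD, n = 5) to 1426 ± 163 (SD, n = 5), a fall of 11.3-fold (adjusted p = 1.84e-14). The kinase Mylk4 fell 10.2-fold, the carboxylesterase Ces1d 10.4-fold and the secreted protein Dkk3 8.01-fold. Falls were smaller for Aebp1, a collagen-binding protein, at 6.36-fold, the natriuretic peptide receptor Npr3 4.86-fold and the scavenger receptor Stab2 4.49-fold.

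Smaller parts of other lists passed in BKO intact muscle. Of 11 smooth muscle and pericyte markers, 5 were lower (6 over the list alone; camera adjusted p = 0.0169; adjusted p = 0.407 with an estimated correlation). Pdgfrb changed by -0.37 ± 0.08, Cspg4 by -0.44 ± 0.10 and Lmod1 by -0.79 ± 0.18. Of 10 fibro-adipogenic progenitor markers, 4 were lower, also over the list alone (camera adjusted p = 0.0335; adjusted p = 0.546 with an estimated correlation). This call ended without WT intact library 4 or BKO intact library 3 or 5 (adjusted p up to 0.147). None of 15 endothelial markers, 13 macrophage markers, 7 MHC class II genes and 11 hypoxia response genes passed, over all genes or over the list alone, nor did their camera tests (adjusted p = 0.305, 0.683, 0.517 and 0.913). Denervation genes were 4 higher and 2 lower of 10 (camera adjusted p = 0.0894). The acetylcholine receptor subunits Chrna1 and Chrnb1 were at 0.96 ± 0.13 and 1.11 ± 0.11. Atrophy genes were 4 higher and 2 lower of 16 (camera adjusted p = 0.647). The ubiquitin ligase Trim63 was at 0.91 ± 0.11. Fast fibre genes were 2 higher and 2 lower of 13 (camera adjusted p = 0.635). Mylpf was at 0.66 ± 0.09 and Mylk2 at -0.68 ± 0.09. The calcium buffer Casq2, at 1.67 ± 0.12, was the 1 of 11 slow fibre genes that passed (camera adjusted p = 0.353). Glycolysis genes were 5 higher and 3 lower of 15 (5 and 4 over the list alone; camera adjusted p = 0.936). The pyruvate kinase Pkm was at 0.52 ± 0.08 and hexokinase Hk2 at -0.83 ± 0.13. Immediate early genes were 2 higher and 3 lower of 10 (camera adjusted p = 0.341), Jun falling from 754 ± 150 (SD, n = 5) to 334 ± 10.9 (SD, n = 5) normalized counts and Atf3 rising by 1.55 ± 0.31.

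Knockout in ligated limbs gave 1084 genes, 510 higher and 574 lower in BKO (136 and 111 by at least 2-fold). Most genes activated by BMAL1-CLOCK were lower in BKO here too, with Nr1d2 at 1592 ± 96.3 (SD, n = 4) normalized counts in WT and 508 ± 68.5 (SD, n = 4) in BKO, and Bmal1 itself was 4.15-fold higher in BKO. Of 10 adipocyte and 13 macrophage markers, 3 each were lower in BKO (Car3 among the adipocyte markers), and neither camera call held with an estimated correlation (adjusted p = 0.32 for both). By fry both lists passed (adjusted p = 0.00247 and 0.0317). Cdkn1a was 9.27-fold higher, at 678 ± 67.7 (SD, n = 4) against 80.2 ± 42.9 (SD, n = 4) normalized counts. Of the genes that passed in both limbs, 213 were higher in both, 234 lower in both and 33 opposite (43.7 and 56.0 by chance for the same direction). Pearson's r of the log2 fold changes across genes, which are not independent replicates, was 0.302.

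Of 13 genes activated by BMAL1-CLOCK, 11 were lower in BKO ligated muscle (12 over the list alone; camera adjusted p = 2.38e-17; adjusted p = 0.000617 with an estimated correlation). It was the only list whose call held with an estimated correlation, here and in intact limbs. Dbp changed by -1.47 ± 0.13, Tef by -1.14 ± 0.10 and the deubiquitinase Usp2 by -1.39 ± 0.16. Of 6 genes repressed by REV-ERB, 3 were higher and 1 lower, also over the list alone (camera adjusted p = 0.00235; adjusted p = 0.129 with an estimated correlation). Clock was at 1.32 ± 0.08 and Nfil3 at 1.80 ± 0.15. Of 10 adipocyte markers, 3 were lower (9 over the list alone), with a median of -1.21 (camera adjusted p = 6.93e-06; adjusted p = 0.32 with an estimated correlation). Among these 3 were the hormone-sensitive lipase Lipe, at -0.87 ± 0.22, and Car3, at -1.84 ± 0.13. In WT intact muscle Car3 stood at 16166 normalized counts and the adipocyte marker Plin1 at 6.12, so the change of Car3 need not reflect fat. Of 13 macrophage markers, 3 were lower (7 over the list alone; camera adjusted p = 0.000605; adjusted p = 0.32 with an estimated correlation). The growth factor receptor Csf1r was at -0.90 ± 0.21 and the complement chain C1qc at -0.96 ± 0.23. Of 10 fibro-adipogenic progenitor markers, 3 were lower (4 over the list alone; camera adjusted p = 0.000996; adjusted p = 0.32 with an estimated correlation). The matrix protein Dpt was at -0.86 ± 0.15. Immediate early genes were 2 higher of 10 (6 over the list alone; camera adjusted p = 0.00732; adjusted p = 0.32 with an estimated correlation). Fos was at 1.54 ± 0.26. Slow fibre genes passed by camera (adjusted p = 0.000996; adjusted p = 0.32 with an estimated correlation). Casq2, at 1.72 ± 0.14, was the 1 of 11 members that passed by itself.

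Among the largest changes in BKO ligated muscle, the micropeptide Mrln, an inhibitor of the calcium pump, rose by 2.44 ± 0.17, the ubiquitin ligase component Wsb1 by 2.28 ± 0.16, Tead4 by 2.28 ± 0.19, Dupd1 by 2.20 ± 0.13 and Ighm by 2.28 ± 0.29. Mylk4 (chromosome 13, 32700834 to 32783954) fell 8.93-fold, from 10461 ± 1221 (SD, n = 4) to 1198 ± 306 (SD, n = 4) normalized counts, the lipogenic regulator Mid1ip1 6.64-fold, the glutamine synthetase Glul 3.61-fold, Car3 3.57-fold and the monoamine oxidase Maob 3.45-fold. Oxidative phosphorylation genes were 1 higher of 34 (camera adjusted p = 0.499). Tricarboxylic acid cycle genes were 1 higher and 1 lower of 14 (0.579) and fatty acid oxidation genes 3 higher and 3 lower of 17 (0.579), with Pdk4 at 1.85 ± 0.22 and the carnitine carrier Slc25a20 at -0.86 ± 0.13. None of 15 endothelial markers, 11 smooth muscle and pericyte markers, 20 extracellular matrix genes and 7 tendon markers passed, over all genes or over the list alone (camera adjusted p = 0.125, 0.294, 0.0682 and 0.535). Denervation genes were 2 higher and 1 lower of 10 (camera adjusted p = 0.341), and atrophy genes 4 higher and 4 lower of 16 (4 and 5 over the list alone; 0.785). Trim63 changed by 1.17 ± 0.13 and the autophagy gene Map1lc3a by -0.76 ± 0.12. Hypoxia response genes were 1 higher and 1 lower of 11 (camera adjusted p = 0.306). The vessel growth factor Vegfa was at 0.64 ± 0.14 and Bnip3 at -0.47 ± 0.10. Camera also passed myogenic (1 higher of 13, 3 over the list alone, adjusted p = 0.0352), fast fibre (3 higher and 1 lower of 13, 5 and 2 over the list alone, 0.0352), MHC class II (0 of 7, 2 lower over the list alone, 0.037), glycolysis (1 higher and 3 lower of 15, 1 and 6 over the list alone, 0.0403) and oxidative stress genes (4 lower of 12, 1 higher and 5 lower over the list alone, 0.0345), none with an estimated correlation (adjusted p = 0.32, 0.584, 0.584, 0.584 and 0.32). Each of these 5 calls also ended when certain single libraries were left out. For myogenic genes these were WT ligated 4 or 5 or BKO ligated 2 or 6 (adjusted p up to 0.128) and for fast fibre genes WT ligated 4 or 6 or BKO ligated 2 or 6 (up to 0.167). For MHC class II they were WT ligated 2 or 4 or BKO ligated 2 (up to 0.134), for glycolysis WT ligated 5 or 6 or BKO ligated 4 (up to 0.246) and for oxidative stress WT ligated 2 (0.0555). Without the 2 BKO ligated libraries with most mt-Rnr2 reads (51.9% and 55.5%), 616 genes passed, a fit chosen after seeing the data.

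Ligation in WT asked how the muscle downstream of the ligated artery differed from the intact muscle 36 days after surgery. Most adipocyte, extracellular matrix and endothelial markers rose. The camera calls of these lists ended with an estimated correlation (adjusted p = 0.145, 0.145 and 0.236). By fry the lists passed (adjusted p = 5.52e-08, 3.92e-07 and 3.57e-06). Cfd, the adipocyte protein adipsin (chromosome 10, 79890853 to 79892655), went from 50.5 ± 25.9 (SD, n = 5) to 2305 ± 662 (SD, n = 4) normalized counts, and the collagen gene Col1a1 from 1002 ± 241 (SD, n = 5) to 3367 ± 300 (SD, n = 4). Of 13 fast fibre genes, 9 were lower (adjusted p = 0.388 with an estimated correlation), the troponin gene Tnnc2 going from 47117 ± 1657 (SD, n = 5) to 25311 ± 2360 (SD, n = 4). In all, 4880 genes passed, 2295 higher and 2585 lower in ligated muscle (716 and 423 by at least 2-fold). The share of reads from mt-Rnr2 was higher and that from mitochondrially encoded mRNAs lower (9.35% ± 0.85 (SD, n = 5) in intact and 4.57% ± 0.13 (SD, n = 4) in ligated muscle). By normalized counts mt-Rnr2 did not pass (0.15 ± 0.22, limma adjusted p = 0.622).

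All 10 adipocyte markers were higher in WT ligated muscle, also over the list alone, with a median of 4.34 (camera adjusted p = 4.28e-11; adjusted p = 0.145 with an estimated correlation). The lipid droplet protein Cidec rose by 5.64 ± 0.45 and the hormone Adipoq by 5.23 ± 0.54. The fatty acid desaturase Scd1 rose by 4.61 ± 0.31. Of 20 extracellular matrix genes, 17 were higher (20 over the list alone; camera adjusted p = 2.43e-11; adjusted p = 0.145 with an estimated correlation). Col1a1 changed by 1.78 ± 0.14, Col3a1 by 2.13 ± 0.15 and Sparc, a collagen-binding glycoprotein, by 1.58 ± 0.09. Fibro-adipogenic progenitor markers were 6 higher of 10 (7 over the list alone; camera adjusted p = 0.0057; adjusted p = 0.39 with an estimated correlation). Dpt was at 1.11 ± 0.15 and Cd34 at 0.79 ± 0.12. Tendon markers were 2 higher and 1 lower of 7 (3 and 1 over the list alone; camera adjusted p = 0.388). Tnmd was at 1.97 ± 0.40.

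Of 15 endothelial markers, 12 were higher, also over the list alone (camera adjusted p = 1.26e-06; adjusted p = 0.236 with an estimated correlation). The adhesion molecule Pecam1 went from 446 ± 50.9 (SD, n = 5) to 896 ± 125 (SD, n = 4) normalized counts, the tight junction gene Cldn5 changed by 1.86 ± 0.18 and the receptor Tie1 by 1.39 ± 0.14. Of 12 angiogenic factors, 7 were higher and 3 lower, also over the list alone (camera adjusted p = 0.053). The peptide Apln changed by 2.11 ± 0.26 and the nitric oxide synthase Nos3 by 1.01 ± 0.14. Smooth muscle and pericyte markers were 5 higher and 2 lower of 11 (camera adjusted p = 0.2). Pdgfrb was at 1.01 ± 0.09 and Cspg4 at 1.06 ± 0.11. Hypoxia response genes were 1 higher and 4 lower of 11 (2 and 4 over the list alone; camera adjusted p = 0.965), but 3 higher and 1 lower with quantile normalization. Of 13 macrophage markers, 8 were higher and 1 lower (11 and 1 over the list alone; camera adjusted p = 0.00458; adjusted p = 0.413 with an estimated correlation). The lysozyme Lyz2 changed by 1.52 ± 0.19, Mpeg1 by 2.11 ± 0.39 and the scavenger receptor Cd163 by -1.53 ± 0.23. MHC class II genes were 6 higher of 7, also over the list alone (camera adjusted p = 0.00402; adjusted p = 0.39 with an estimated correlation). H2-Aa was at 1.64 ± 0.29 and Cd74 at 1.36 ± 0.25. None of 13 lymphocyte markers (highest mean 4.18) and 10 neutrophil markers (9 below, 1 absent, highest mean 6.92) reached the mean of 10 needed for a test. Of 4 cytokine and chemokine genes tested, 2 were higher (Lgals3, galectin 3, by 2.75 ± 0.37 and Ccl6 by 1.81 ± 0.34). Of 9 interferon response genes, 4 were higher, among them Bst2 by 1.67 ± 0.26 and Irf7 by 1.55 ± 0.31. Immediate early genes, which respond within minutes to stimuli, were 7 higher and 1 lower of 10, also over the list alone (camera adjusted p = 0.00458; adjusted p = 0.348 with an estimated correlation). Fos went from 22.1 ± 5.96 (SD, n = 5) to 171 ± 60.8 (SD, n = 4) normalized counts, and Junb rose by 1.45 ± 0.24.

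Of 13 fast fibre genes in WT ligated muscle, 9 were lower and 1 higher, also over the list alone (camera adjusted p = 0.000349; adjusted p = 0.388 with an estimated correlation). With quantile normalization 3 were lower and 2 higher (camera adjusted p = 0.771). Slow fibre genes were 1 higher and 2 lower of 11 (camera adjusted p = 0.734). The calcium pump Atp2a2 was at 1.02 ± 0.15. Myogenic genes were 6 higher and 3 lower of 13 (7 and 3 over the list alone; camera adjusted p = 0.201), Myh8, the perinatal myosin, whose near-identical neighbours leave its level uncertain, going from 41.6 ± 8.16 (SD, n = 5) to 249 ± 85.7 (SD, n = 4) and the satellite cell cadherin Cdh15 changing by -1.05 ± 0.15. Denervation genes were 4 higher and 2 lower of 10 (camera adjusted p = 0.354). The calcium pump inhibitor Sln was at 3.87 ± 0.53 and the receptor kinase Musk at -1.28 ± 0.21. Atrophy genes were 5 higher and 5 lower of 16 (camera adjusted p = 0.905), the ubiquitin ligase Fbxo32 falling from 2636 ± 447 (SD, n = 5) to 890 ± 109 (SD, n = 4) and Trim63 changing by -0.66 ± 0.12. Cell cycle genes were 3 higher and 1 lower of 8 (camera adjusted p = 0.383). The ribonucleotide reductase Rrm2 was at 1.92 ± 0.41 and the kinase Aurka at -2.63 ± 0.23. Schwann cell markers were 2 higher of 7 (camera adjusted p = 0.201) and blood cell markers 0 of 5 (0.383).

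Of 34 oxidative phosphorylation genes, 16 were higher and 2 lower in WT ligated muscle (18 and 3 over the list alone; camera adjusted p = 0.00402; adjusted p = 0.574 with an estimated correlation), with a median of 0.21. With quantile normalization 23 were higher and 1 lower, with a median of 0.39. Ndufa2 changed by 0.94 ± 0.09, Uqcrfs1 of complex III by 0.73 ± 0.09 and Cox6a2, the muscle form of a complex IV subunit, by -0.85 ± 0.12. Tricarboxylic acid cycle genes were 7 higher and 2 lower of 14 (8 and 2 over the list alone), but 11 higher and 0 lower with quantile normalization. Mdh2 was at 0.49 ± 0.08. Glycolysis genes were 1 higher and 3 lower of 15 (camera adjusted p = 0.606), but 11 higher and 2 lower with quantile normalization. Fatty acid oxidation genes were 1 higher and 3 lower of 17 (0.466), but 5 and 3. Pgk1 changed by 0.43 ± 0.08, the fatty acid binding protein Fabp3 by -1.11 ± 0.21 and the lipoprotein lipase Lpl by 0.59 ± 0.15. Oxidative stress response genes were 5 lower of 12 (camera adjusted p = 0.175). Gpx3 was at -0.90 ± 0.14. Bmal1 fell by 1.73 ± 0.18 (adjusted p = 1.95e-07). Of 6 genes repressed by REV-ERB, 4 were lower, also over the list alone (camera adjusted p = 0.0271; adjusted p = 0.251 with an estimated correlation). Rora changed by -0.85 ± 0.09 and Clock by -0.59 ± 0.08. Genes activated by BMAL1-CLOCK were 2 higher and 7 lower of 13, also over the list alone (camera adjusted p = 0.178). Per3 was at 0.68 ± 0.16 and Bhlhe41 at -1.17 ± 0.14. Among the largest falls were the peptide transporter Slc15a5, by 24.7-fold, the small GTPase Rasd2, by 15.5-fold, the phosphatase Dusp26, by 8.21-fold, and Dkk3, by 7.02-fold. Camera calls of 3 lists with camera adjusted p of 0.0372 (cytokines), 0.0404 (interferon) and 0.0435 (tricarboxylic acid cycle) ended with an estimated correlation (adjusted p = 0.251, 0.348 and 0.549). They ended too when single libraries were left out. The libraries were WT ligated 2 for cytokines (0.0512), WT intact 3 and WT ligated 2 and 4 for interferon (up to 0.0975). For the tricarboxylic acid cycle they were WT intact 3 and 4, WT ligated 5 and 6 and BKO intact 5 (up to 0.0914).

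**Figure D2:**
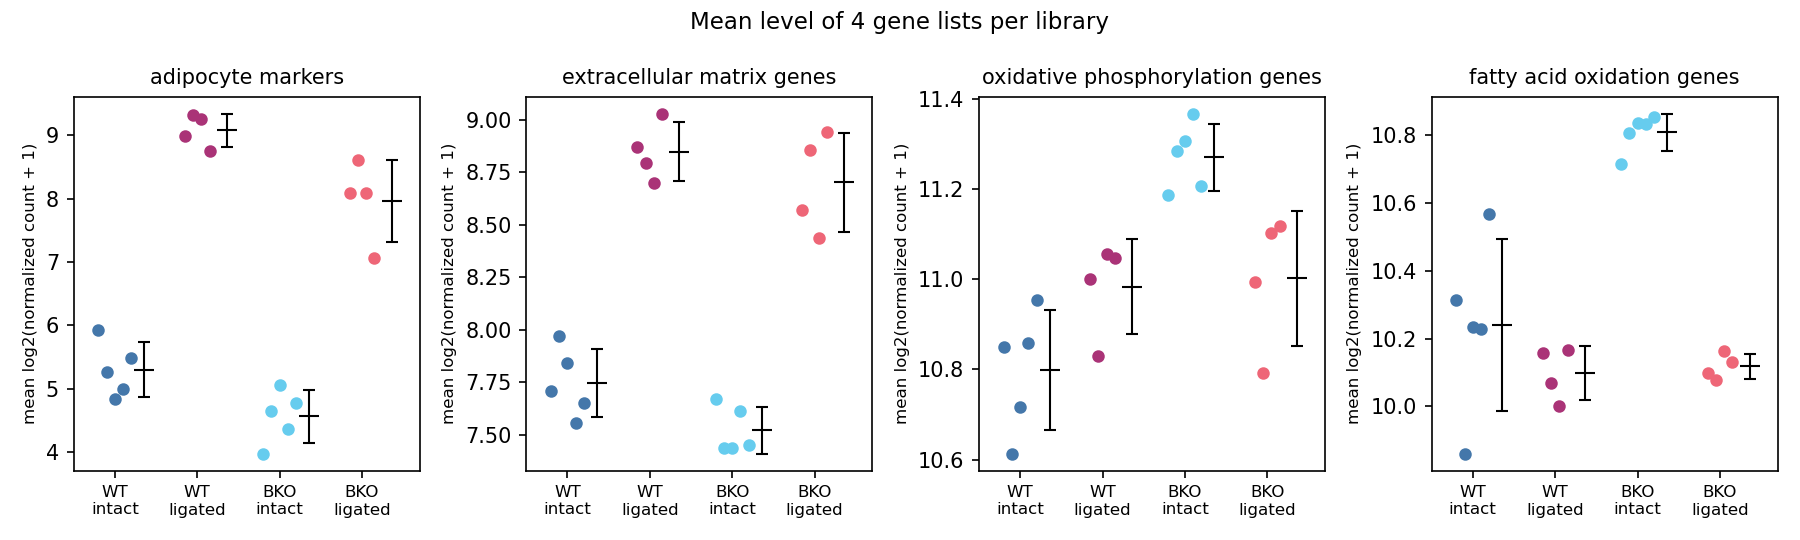
Mean log2(normalized count + 1) over the tested members of 4 gene lists in each of the 18 libraries, by genotype and limb; the bars show the mean ± SD of 5 intact or 4 ligated libraries, and the axes do not start at 0. Adipocyte markers lay between 3.98 and 5.93 in intact and between 7.06 and 9.31 in ligated muscle, and oxidative phosphorylation genes lay between 11.19 and 11.37 in BKO intact muscle, above all WT intact libraries.

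Ligation in BKO gave 5790 genes, 2713 higher and 3077 lower in ligated muscle (889 and 451 by at least 2-fold). Most adipocyte, extracellular matrix and endothelial markers rose here too, and again the camera calls ended with an estimated correlation (adjusted p = 0.131, 0.131 and 0.187). By fry these lists passed (adjusted p = 1.07e-07, 1.94e-07 and 2.35e-06). Cfd went from 33.0 ± 18.7 (SD, n = 5) to 1293 ± 675 (SD, n = 4) normalized counts and Col1a1 from 834 ± 52.2 (SD, n = 5) to 2924 ± 542 (SD, n = 4). Of 17 fatty acid oxidation genes, 15 were lower (adjusted p = 0.317 with an estimated correlation), Acadm going from 3479 ± 299 (SD, n = 5) to 1840 ± 279 (SD, n = 4). Fos, an immediate early gene, rose from 25.9 ± 6.25 (SD, n = 5) to 472 ± 76.1 (SD, n = 4). Mitochondrially encoded mRNAs took 7.77% ± 0.49 (SD, n = 5) of the reads in BKO intact and 3.92% ± 0.37 (SD, n = 4) in BKO ligated muscle.

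All 10 adipocyte markers were higher in BKO ligated muscle, also over the list alone, with a median of 3.73 (camera adjusted p = 1.66e-09; adjusted p = 0.131 with an estimated correlation). Adipoq changed by 5.10 ± 0.54 and Plin1 from 3.96 ± 2.33 (SD, n = 5) to 153 ± 77.6 (SD, n = 4) normalized counts. Of 20 extracellular matrix genes, 18 were higher, also over the list alone (camera adjusted p = 1.47e-10; adjusted p = 0.131 with an estimated correlation). Col3a1 changed by 1.78 ± 0.15 and the thrombospondin Thbs1 by 1.83 ± 0.15. Of 15 endothelial markers, 13 were higher, also over the list alone (camera adjusted p = 1.33e-06; adjusted p = 0.187 with an estimated correlation). Pecam1 changed by 1.07 ± 0.12 and Cldn5 by 1.61 ± 0.18. Smooth muscle and pericyte markers were 5 higher and 2 lower of 11 (camera adjusted p = 0.0666), but 5 higher and 0 lower with quantile normalization. Pdgfrb was at 1.22 ± 0.09 and the receptor Notch3 at 1.52 ± 0.15. Angiogenic factors were 5 higher and 2 lower of 12 (6 and 2 over the list alone; camera adjusted p = 0.169). Nos3 was at 1.02 ± 0.14 and Angpt1 at -0.95 ± 0.12. Macrophage markers were 3 higher and 1 lower of 13 (camera adjusted p = 0.361). Cd163 was at -1.72 ± 0.23. MHC class II genes were 1 higher of 7 (camera adjusted p = 0.277) and interferon response genes 3 higher of 9 (0.152), with Ifit2 at 0.82 ± 0.20. Immediate early genes were 8 higher of 10, also over the list alone (camera adjusted p = 3.12e-06; adjusted p = 0.131 with an estimated correlation). Fosb rose by 6.01 ± 0.62, the largest rise among the named genes of this comparison.

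Of 17 fatty acid oxidation genes, 15 were lower in BKO ligated muscle, also over the list alone, with a median of -0.65 (camera adjusted p = 1.24e-06; adjusted p = 0.317 with an estimated correlation). Slc25a20 was at -1.10 ± 0.12. Oxidative phosphorylation genes were 14 lower and 3 higher of 34, also over the list alone, with a median of -0.17 (camera adjusted p = 0.0045; adjusted p = 0.721 with an estimated correlation). That median was 0.002 with quantile normalization, and the call ended there (0.752) and after a correction for transcript length and GC content chosen after seeing the data (0.621). Cox6a2 changed by -1.49 ± 0.12 and Ndufa5 by -0.66 ± 0.08. Tricarboxylic acid cycle genes were 2 higher and 7 lower of 14 (camera adjusted p = 0.169), but 4 higher and 4 lower with quantile normalization. Idh3b was at -0.65 ± 0.08. Glycolysis genes were 7 lower of 15 (camera adjusted p = 0.0549), but 5 higher and 2 lower with quantile normalization, with the glucose transporter Slc2a4 at -0.76 ± 0.11. Fast fibre genes were 8 lower and 2 higher of 13 (9 and 2 over the list alone; camera adjusted p = 0.0124; adjusted p = 0.52 with an estimated correlation), but 2 and 2 with quantile normalization, where the direction of the camera test turned (0.951). Tnnc2 (chromosome 2, 164777161 to 164779967) fell by 0.96 ± 0.07. Slow fibre genes were 2 higher and 2 lower of 11 (camera adjusted p = 0.493). Atp2a2 was at 1.58 ± 0.15. Of 13 myogenic genes, 7 were higher and 1 lower (9 and 1 over the list alone; camera adjusted p = 0.0214; adjusted p = 0.351 with an estimated correlation). Myh8 changed by 2.44 ± 0.30, the satellite cell factor Pax7 by 1.35 ± 0.31 and the satellite cell receptor Megf10 by 1.16 ± 0.27.

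Denervation genes were 3 higher and 2 lower of 10 in BKO ligated muscle (3 and 3 over the list alone; camera adjusted p = 0.887). Sln was at 3.96 ± 0.53 and the transcription factor Runx1 at 1.94 ± 0.29. Atrophy genes were 4 higher and 6 lower of 16 (camera adjusted p = 0.7). Cdkn1a changed by 1.56 ± 0.34 and Fbxo32 by -1.37 ± 0.14. Hypoxia response genes were 2 higher and 4 lower of 11 (camera adjusted p = 0.7). The kinase Pdk1 was at -0.98 ± 0.16. Cell cycle genes were 2 higher and 2 lower of 8 (camera adjusted p = 0.99) and Schwann cell markers 1 lower of 7 (0.7), with Mbp at -0.76 ± 0.17. Genes activated by BMAL1-CLOCK were 5 higher and 1 lower of 13, also over the list alone (camera adjusted p = 0.361). Per1 changed by 1.16 ± 0.14 and Per2 by 0.78 ± 0.15. Bmal1 was at 0.48 ± 0.18 (adjusted p = 0.0291), a call that ended without BKO intact library 1 or 5 or BKO ligated library 2 or 5 (adjusted p up to 0.0941) with quantile normalization (0.0908) and with no filter (0.0555). The transcription cofactor Dach2 fell 77.0-fold, the ketone body enzyme Bdh1 33.2-fold and Dusp26 27.2-fold. Camera also passed fibro-adipogenic progenitor (5 higher of 10, 6 over the list alone, adjusted p = 0.044), tendon (5 higher of 7, 0.0215) and oxidative stress genes (5 lower of 12, 0.0344), none with an estimated correlation (adjusted p = 0.52, 0.389 and 0.389). Single libraries ended these 3 calls too: BKO intact 3 or 5 or BKO ligated 4 or 6 for the progenitor markers (up to 0.111), BKO ligated 6 for tendon (0.0503) and BKO intact 2 for oxidative stress (0.0562). Among their members, the cartilage matrix protein Comp changed by 1.99 ± 0.33, the catalase gene Cat by -1.22 ± 0.13 and the glutathione transferase Gsta4 by -1.83 ± 0.18.

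The interaction asked whether the response to ligation differed between genotypes. It did for 737 genes, 373 with a more positive and 364 with a more negative log2 change in BKO. Many nuclear genes of the respiratory chain and of fatty acid oxidation had the more negative change in BKO, and some immediate early and clock genes the more positive one. With an estimated correlation none of these 4 lists passed (adjusted p = 0.241 for each). Sdhb went from 1970 ± 244 (SD, n = 5) to 2274 ± 136 (SD, n = 4) normalized counts with ligation in WT and from 2818 ± 229 (SD, n = 5) to 1897 ± 305 (SD, n = 4) in BKO, an interaction of -0.80 ± 0.15 (adjusted p = 0.0045). Bmal1 had an interaction of 2.21 ± 0.25 (adjusted p = 8.74e-05).

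Most of the response was shared. Of the genes that passed in both genotypes, 1510 were higher in both, 1849 lower in both and 63 opposite (508 and 649 by chance for the same direction). The log2 fold changes had a Pearson r of 0.752 and a Spearman rho of 0.713 across genes, which are not independent replicates. Of the 737 interaction genes, 63 passed in opposite directions, 123 passed in the same direction, 339 passed with ligation in BKO and not in WT and 212 in WT and not in BKO. Adipocyte, extracellular matrix and endothelial lists did not pass (camera adjusted p = 0.403, 0.861 and 0.805), with 1 higher and 1 lower of 10, 1 higher of 20 and 0 of 15 members past the test (1 higher and 2 lower, 2 higher and 0 over the lists alone). The adipocyte member that was higher was Car3, of muscle and fat.

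**Figure D3:**
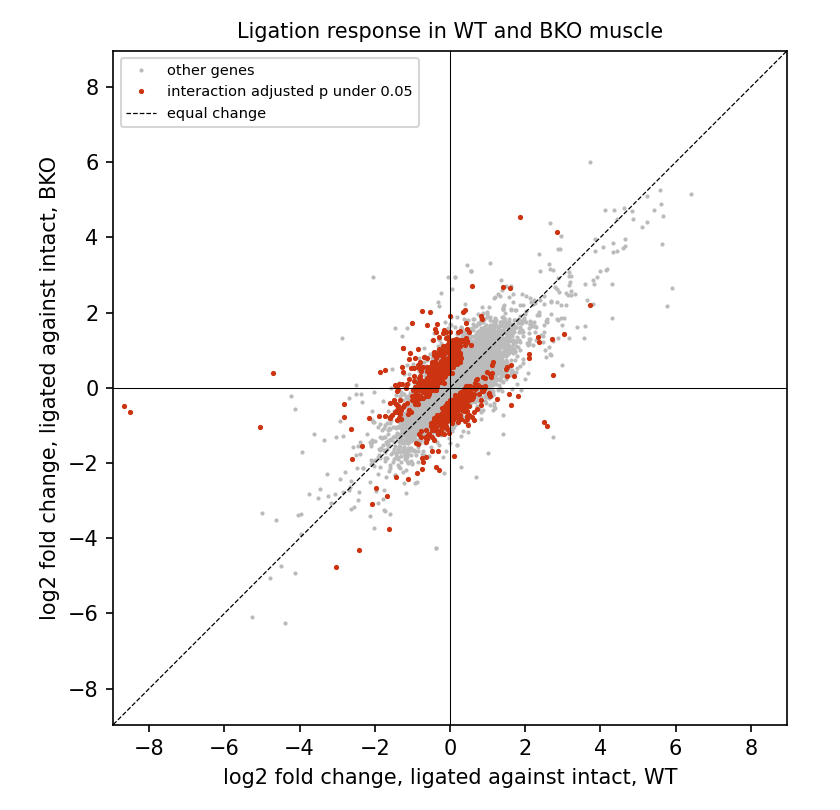
Log2 fold change of ligated against intact muscle in WT (horizontal) and in BKO (vertical) for the 12262 genes tested, each point 1 gene; the 737 genes with an interaction are in red and the dashed line marks an equal change. The points follow the dashed line with a Pearson r of 0.752, and the red points lie off it on both sides.

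Of 34 oxidative phosphorylation genes, 19 had a negative interaction (32 over the list alone), with a median of -0.45 (camera adjusted p = 2.79e-19; adjusted p = 0.241 with an estimated correlation). Atp5o was at -0.51 ± 0.11, Ndufs8 at -0.62 ± 0.13 and Sdhd at -0.79 ± 0.18. Fatty acid oxidation genes were 8 negative of 17 (13 over the list alone; camera adjusted p = 2.87e-10; adjusted p = 0.241 with an estimated correlation). Slc25a20 was at -1.03 ± 0.17 and the acyl-CoA dehydrogenases Acads and Acadvl at -0.77 ± 0.14 and -0.78 ± 0.16. Tricarboxylic acid cycle genes were 4 negative of 14 (11 over the list alone; camera adjusted p = 1.29e-06; adjusted p = 0.258 with an estimated correlation), but 7 with quantile normalization. Longer transcripts had the more positive interaction, with a Spearman correlation across genes of 0.283 with transcript length. Ribosomal protein genes, which are short, had a median interaction of -0.30 (12 negative and 0 positive of 76). The median of the oxidative phosphorylation genes lay at percentile 0 of 10000 random lists matched on length, GC content and mean level, of which the central 95% were negative too (-0.32 to -0.11). The random lists drew genes singly, while the members of this list are correlated, so the percentile can overstate the contrast. Immediate early genes were 2 positive of 10 (5 over the list alone; camera adjusted p = 0.000499; adjusted p = 0.241 with an estimated correlation). Jun went from 754 ± 150 (SD, n = 5) to 633 ± 83.9 (SD, n = 4) with ligation in WT and from 334 ± 10.9 (SD, n = 5) to 634 ± 115 (SD, n = 4) in BKO. Genes activated by BMAL1-CLOCK were 2 positive of 13, also over the list alone (camera adjusted p = 0.000586; adjusted p = 0.241 with an estimated correlation). Per1 was at 1.21 ± 0.19 and Bhlhe41 at 1.16 ± 0.20. Macrophage markers were 2 negative of 13 (3 over the list alone; camera adjusted p = 0.0201; adjusted p = 0.503 with an estimated correlation). Lgals3, counted here with the cytokine and chemokine genes, had an interaction of -2.41 ± 0.53, going from 8.47 ± 6.77 (SD, n = 5) to 52.3 ± 11.6 (SD, n = 4) normalized counts in WT and from 29.0 ± 10.1 (SD, n = 5) to 35.0 ± 1.46 (SD, n = 4) in BKO.

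Among single genes of the interaction, Actc1 went from 227 ± 94.3 (SD, n = 5) to 1259 ± 361 (SD, n = 4) normalized counts with ligation in WT and from 3045 ± 939 (SD, n = 5) to 1723 ± 814 (SD, n = 4) in BKO (-3.43 ± 0.45, adjusted p = 0.000479). Car3 went from 16166 ± 2429 (SD, n = 5) to 21294 ± 2836 (SD, n = 4) in WT and from 1426 ± 163 (SD, n = 5) to 5957 ± 809 (SD, n = 4) in BKO (1.66 ± 0.17, adjusted p = 4.96e-05). The mitochondrial leucyl-tRNA synthetase Lars2 was at 2.77 ± 0.51, the sodium pump subunit Atp1b2 at 1.89 ± 0.32, the microtubule protein Map1a at 1.84 ± 0.31 and the histone methyltransferase Kmt2d at 1.70 ± 0.24. Dusp26 was at -1.73 ± 0.30, Mybph at -1.60 ± 0.33, the glucose transporter regulator Trarg1 at -1.54 ± 0.37 and the amylase Amy1, a member of a family of close copies and so uncertain, at -1.40 ± 0.21. The count of 737 fell to 402 without WT ligated library 2 and to 461 without WT ligated library 5. It was 269 without the 2 BKO ligated libraries with most mt-Rnr2 reads, 463 after the correction for transcript length and GC content and 1183 with DESeq2. The calls of the single genes named here were not followed under these settings. Camera calls of MHC class II (adjusted p = 0.0226), cytokine (0.0292), tendon (0.0292), Schwann cell (0.032) and blood cell genes (0.0292) ended with an estimated correlation (adjusted p = 0.503, 0.241, 0.422, 0.361 and 0.503). They ended too without single libraries: for MHC class II BKO ligated 2 (0.051) and for cytokines WT intact 6, WT ligated 4, BKO intact 5 or BKO ligated 6 (up to 0.0644). For tendon these were WT intact 6, WT ligated 4, BKO intact 3 or BKO ligated 6 (up to 0.161). For Schwann cell genes they were WT intact 6, WT ligated 4 or 6, BKO intact 5 or BKO ligated 6 (up to 0.134), and for blood cell genes WT intact 3, BKO intact 2 or BKO ligated 6 (up to 0.0876).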

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

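Of the tests printed in this part, the 3 on Bmal1, the B-cell test on Ighm and the correction for length and GC content were chosen only after their result was seen; the others were written before. In groups of 4 or 5 libraries, 8 of 216 measured groups held 1 library far from the others by Dixon's gap test, where chance flags about 1 in 20 groups (10.8 of these). BKO ligated library 5 had 25.6 M reads (others 19.3 to 20.3 M), and BKO intact library 4 had 0.724% of its reads on the unnamed gene ENSMUSG00000045999 (others 0.0504% to 0.208%). By mean log2 of a list, WT intact library 2 was low in atrophy genes (7.79; others 8.02 to 8.09), BKO ligated library 4 in oxidative stress genes (6.996; others 7.15 to 7.16) and BKO ligated library 6 in immediate early genes (7.70; others 7.91 to 7.92). Ighm stood at 403 in WT intact library 2 (others 229 to 267) and at 242 in BKO ligated library 5 (others 590 to 660), and Jun at 1014 in WT intact library 4 (others 638 to 730).

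The remaining results differed between genotypes by a test of the difference itself, the ligation effect in BKO minus that in WT. It passed for 737 genes. Among the genes printed, it was positive for Arntl (2.21), Lars2 (2.77), Mkx (2.72), Atp1b2 (1.89), Map1a (1.84), Hectd4 (1.72), Kmt2d (1.70), Car3 (1.66), Per1 (1.21), Bhlhe41 (1.16), Jun (1.15) and Thbs1 (0.97). It was negative for Actc1 (-3.43), Lgals3 (-2.41), Dusp26 (-1.73), Mybph (-1.60), Trarg1 (-1.54), Amy1 (-1.40), Gsta4 (-1.20), Slc25a20 (-1.03), Chrna1 (-0.83), Sdhb (-0.80), Sdhd (-0.79), Acadvl (-0.78), Acads (-0.77), Hadhb (-0.76), Ndufs8 (-0.62) and Atp5o (-0.51). By camera adjusted p it passed for 11 lists: positive for clock genes activated by BMAL1-CLOCK (0.000586), immediate early genes (0.000499) and tendon markers (0.0292), and negative for oxidative phosphorylation (2.79e-19), fatty acid oxidation (2.87e-10), tricarboxylic acid cycle (1.29e-06), macrophage (0.0201), MHC class II (0.0226), cytokine (0.0292), blood cell (0.0292) and Schwann cell genes (0.032). None of the 11 passed with an estimated correlation (adjusted p = 0.241 to 0.503), and the MHC class II, cytokine, tendon, Schwann cell and blood cell calls also ended without single libraries, BKO ligated 2 for MHC class II (0.051) and BKO ligated 6 among others for the other 4 (adjusted p up to 0.161).

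Oxidative phosphorylation genes were higher in BKO intact muscle (adjusted p = 0.179 with an estimated correlation), where shorter transcripts were higher too, so a bias by transcript length and GC content was set against an effect of genotype. The median of the list, 0.50, lay at percentile 100 of 10000 random lists matched on length, GC content and mean level. The central 95% of these lists ran from 0.04 to 0.26, so they were higher too. Their genes were drawn singly, while the members of the list had an estimated correlation of 0.659, so the percentile can overstate the contrast. Ribosomal protein genes, also short, had a median of 0.0773. After correction for length and GC content 29 of 34 members were still higher, with a median of 0.38. In 10 fits without 1 library the median stayed between 0.45 and 0.54 with at least 29 of 34 members higher, and camera adjusted p, at the preset correlation, reached at most 1.92e-23. The median was lower after the correction (0.38 against 0.50), so length and GC bias can account for part of the rise. By these tests neither that bias nor 1 library accounts for all of it, while a bias in how the libraries of the genotypes were made was not tested.

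The total reads of Bmal1 were not lower in the libraries labelled BKO, and the labels give the Cre genotype the other way round, +/+ for controls and -/- for knockouts. A swap of the labels predicted higher BMAL1-CLOCK targets in BKO, but their median was below 0 in both limbs, -1.14 in the limb nearer to 0. The levels of these genes also depend on the time of day of collection, which is not given, so their median alone does not settle the labels. Loss of repression by REV-ERB stays open: the 6 other genes it represses changed in both directions, with a median of 0.74 in the limb nearer to 0, while Bmal1 changed by -0.16 in intact and 2.05 in ligated limbs. Reads from the part of the gene that was not deleted cannot be told apart from reads of the whole gene, since the table holds 0 counts per exon.

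Ighm was higher in BKO intact muscle, and so was Igha (3.35), while the rises of Igkc and Jchain did not pass (adjusted p = 0.107 and 0.108). As the source of the Ighm reads, B or plasma cells predicted light chain reads at least as abundant, but Igkc had 0.00975 reads per Ighm read (132 against 13543 reads). A change of the chromosome region predicted that most neighbours rose, but 10% of the 20 other tested genes within 1 Mb were higher, Nudt14 (0.93) and Igha. All of these genes lay on the same side of Ighm, so the region on its other side was not tested. Of the heavy chain genes among them, Igha rose and Ighg2c (-1.59 ± 0.70) did not pass. A few B or plasma cells beside another source of Ighm, and an effect of genotype on Ighm itself, stay open. So does a change limited to immunoglobulin genes or to the side not tested.

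Other splits of the libraries into groups of the same size were set against the real one. For ligation in WT 1 of 100 splits, the real one, gave as many genes (4880; highest other 3002), and for ligation in BKO 1 of 100 (5790; highest other 4580). For knockout in intact limbs it was 1 of 100 (2246; highest other 3), for knockout in ligated limbs 1 of 35 (1084; highest other 361) and for the interaction 1 of 100 (737; highest other 362). In all 5 comparisons no other split tried gave as many genes as the real one. For knockout in ligated limbs 1 of 35 is the lowest share this design allows. For the interaction, genotype was shuffled within each limb, which also breaks up the difference between genotypes. Those splits cannot tell an interaction from that difference, so chance is not excluded there.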

How the results depend on the processing

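The correction for transcript length and GC content (12188 genes, 99.4%) and the fit without the 2 BKO ligated libraries with most mt-Rnr2 reads were chosen after seeing the data; the other settings were planned before. Counts of genes past the test stayed within 1.5 times in 158 recalculations, were lower in 11 and higher in 1. A log2 fold change of at least 1 left 1139 genes for ligation in WT, 1340 for ligation in BKO, 294 for knockout in intact and 247 for knockout in ligated limbs and 170 for the interaction, as that setting adds a condition. Without the 2 BKO ligated libraries, with fewer samples, 616 genes passed for knockout in ligated limbs and 269 for the interaction. The interaction count was 1183 with DESeq2 and 463 after the correction for length and GC content; the cause was not tested. Without 1 library, the counts ranged from 4303 to 4928 for ligation in WT, 5027 to 5864 for ligation in BKO, 1778 to 2313 for knockout in intact limbs, 733 to 1257 for knockout in ligated limbs and 402 to 1015 for the interaction.

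Of the recalculations of 54 list calls, 1110 kept the call (922 of them without 1 library), 131 lost it and 1 turned its direction: fast fibre genes for ligation in BKO with quantile normalization (adjusted p = 0.951); the cause was not tested. The estimated correlation ended 52 of the 54, all but the genes activated by BMAL1-CLOCK for knockout in both limbs. Leaving out 1 library ended calls in 50 recalculations. Fry asks another question than camera, and its passes are counted here as kept calls. By fry 9 did not pass: for knockout in intact limbs fibro-adipogenic progenitor (adjusted p = 0.0511), in ligated limbs myogenic (0.0502), fast fibre (0.125), MHC class II (0.129) and glycolysis genes (0.125), and for the interaction macrophage (0.163), MHC class II (0.163), tendon (0.111) and blood cell genes (0.147). Quantile normalization ended 6: fast fibre (0.771), cytokine (0.0599) and interferon genes (0.111) for ligation in WT, oxidative phosphorylation (0.752) for ligation in BKO, and fast fibre (0.161) and glycolysis genes (0.113) for knockout in ligated limbs. The correction for length and GC content ended 5: oxidative phosphorylation (0.621) and oxidative stress genes (0.102) for ligation in BKO, MHC class II (0.0632) and glycolysis genes (0.227) for knockout in ligated limbs and blood cell genes (0.0609) for the interaction.

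Of the recalculations of the named genes, none of them with edgeR or DESeq2, 6899 kept and 110 lost the call. Of those kept, 4370 were fits without 1 library. The genes were printed because their calls stayed in such fits, so these fits do not test them. Of those lost, 87 were by the condition of a log2 fold change of at least 1 and 4 without 1 library (Bmal1 for ligation in BKO). Quantile normalization ended 4 (Bmal1 for ligation in BKO, Idh3b and Pygm for ligation in WT, Atp2a1 for knockout in intact limbs). Using only the libraries compared ended 3 (Tnnc2, Musk and Txnrd1 for knockout in ligated limbs), no filter 2 (Bmal1 for ligation in BKO, Atp2a1 for knockout in intact limbs) and a pseudocount of 5 ended 1 (Lep for knockout in intact limbs).

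The sample number as a fixed block gave 4434, 4667, 2021, 1029 and, for the interaction, 382 genes, and as a random block 4990, 5857, 2255, 1084 and 812. With the fixed block, 9 list calls did not pass: tricarboxylic acid cycle (adjusted p = 0.0774) and interferon genes (0.0706) for ligation in WT, progenitor (0.0913), tendon (0.103) and oxidative stress genes (0.0563) for ligation in BKO, glycolysis (0.0532) for knockout in ligated limbs, and tendon (0.358), Schwann cell (0.147) and blood cell genes (0.0893) for the interaction. Neither did 9 named genes: Bmal1 (0.108), Megf10 (0.0558) and Myl3 (0.221) for ligation in BKO, and Trarg1 (0.0969), Ndufs8 (0.0609), Mkx (0.145), Thbs1 (0.131), Gsta4 (0.0566) and Chrna1 (0.121) for the interaction. No sign was seen that the numbers pair the samples, which the labels leave open: residuals of 7 intact and ligated pairs of 1 number correlated at -0.064 to 0.048 and those of 8 WT and BKO pairs at -0.055 to 0.121. Depth limits genes near the filter, and only 37.3% of simulated 2-fold interactions were recovered.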

Other observations

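The 13 mRNAs encoded by mitochondrial DNA were 9 lower and 1 higher in WT ligated muscle (median -1.28) and 7 lower and 3 higher in BKO ligated muscle (median -0.46). With quantile normalization they were 9 lower and 1 higher in WT (median -0.53) and 5 lower and 5 higher in BKO (median -0.18). In BKO intact muscle 5 were lower and 8 not past the test, and 3 were lower with quantile normalization. The interaction was positive for 5 of 13 (median 0.49): mt-Nd5, a complex I subunit, changed by -1.28 ± 0.17 with ligation in WT and not in BKO (0.10 ± 0.17), an interaction of 1.37 ± 0.24 (adjusted p = 0.00273). The interactions of mt-Nd2 and mt-Nd4 were 0.97 ± 0.20 and 0.99 ± 0.20. Ribosomal protein genes were 36 lower and 7 higher of 76 in BKO ligated muscle (27 and 9 with quantile normalization) and 21 higher and 17 lower in WT ligated muscle (35 and 7 with quantile normalization).

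Angptl4, an inhibitor of lipoprotein lipase, was chosen after its values were seen. It went from 5.89 ± 1.57 (SD, n = 5) to 40.2 ± 10.9 (SD, n = 4) normalized counts with ligation in WT and from 79.7 ± 40.5 (SD, n = 5) to 38.7 ± 19.3 (SD, n = 4) in BKO, an interaction of -3.60 ± 0.48. The unnamed gene ENSMUSG00000045999, also chosen after its values were seen, had mean normalized counts of 116312 in WT intact, 428971 in WT ligated, 47706 in BKO intact and 758546 in BKO ligated muscle. The Y-linked gene Ddx3y stood at 325 in BKO ligated library 6 (589 to 818 in the other BKO ligated libraries), and Xist had 13 reads in BKO ligated library 4 and at most 1 in every other library.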
